A study of Canis lupus familiaris with 16 samples.

How the data were processed

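Myocardium from the subendocardium of the left ventricle of dogs was compared between the anterior and the lateral wall on 2-colour expression arrays. Per the labels' protocols, total RNA was taken with TRIzol, reverse transcribed and amplified with T7 RNA polymerase, and the RNA of one wall was labelled with Cy3 and that of the other wall with Cy5. Each of the 16 arrays holds both walls of a single animal and carries its own animal label, so the animal is the replicate. The labels place 6 animals in a non-failing group (NF), 5 in a group with dyssynchronous heart failure (DHF) and 5 in a group given cardiac resynchronization therapy (CRT). Cy5 held the lateral wall on 6 arrays (2 in each group) and the anterior wall on the other 10 (4 NF, 3 DHF and 3 CRT).

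The authors deposited 1 value per feature and array on a log2 scale, with no missing value among 42034 features. Background correction, normalization, filters and software are not given in the sources used here. The values are ratios within an array, and the medians of the 16 arrays lie between -0.0036 and 0.0029, so each array was already centred near 0. The features are known by number only, up to 44287, with 2253 numbers absent from the list. No table pairing these numbers with genes was used here, and the reference gene table of the dog assembly UU_Cfam_GSD_1.0 holds no such number. Hence no gene, gene list, cell type marker or genomic position is reported, although such lists had been fixed before the data were examined.

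The log base and the direction of the ratios are not stated and were read from the values. On each array 62.0% to 70.0% of the features share their exact value with another feature. These shared values form runs with the spacing of logarithms of successive whole numbers, as weak whole-number signals in one channel would give. In base 2 the coefficients of a run of the numerator channel and of one of the denominator channel add up to 2.89, the value of 2/ln 2. Of 4324 runs, 87.2% had such a partner within 0.0005, against 1.11% for the sum expected with natural logarithms, 0% with base 10, and 3.84% and 5.53% for sums shifted down or up by 0.05. The larger coefficient lay on the numerator on 6 of 6 arrays with Cy5 on the lateral wall and on the denominator on 10 of 10 arrays with Cy5 on the anterior wall. The deposited values also carry up to 6 significant digits on the former and up to 10 on the latter. On this basis the values were taken as already turned by the authors to one wall over the other. That reading assumes that the coefficient follows the dye and not the wall. The numerator is likely the lateral wall, since Cy5 over Cy3 is the usual ratio; this sign is not settled by the values, and all signs turn together if it is the anterior wall.

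The rule written before the data were examined relied on spike-in probes, which cannot be told by number, or else on which part of the values differs more between the groups. That second criterion gave a mean squared F of 4.53 for the part that keeps its sign across orientations and 5.41 for the part that turns with orientation, where 4.17 is expected with no difference. No feature passed adjusted p 0.05 in either part. The criterion nominally favours the other reading, in which the values still run by dye. The structure of the shared values, examined afterwards, was given precedence, and the counts under the other reading are reported beside the results.

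Each feature's log2 wall ratio was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group and a dye term shared by all groups (lmFit, contrasts.fit and eBayes). All 16 arrays entered the fit, so the groups share their estimate of the spread. Benjamini-Hochberg adjustment ran over the 42034 features in each of 6 contrasts, with adjusted p 0.05 as threshold. On simulated data with 50 changed features per fold size among 42034, the fit recovered 84% of 1.25-fold, 96% of 1.5-fold and 100% of 2-fold changes in the DHF contrast, with 14 false calls. For DHF minus NF it recovered 82%, 94% and 100%, with 11 false calls. These rates depend on the simulated noise and on the number of changed features. In the real data a DHF minus NF difference of 0.35 log2 units (feature 43268), more than 1.25-fold, did not pass. A count of 0 therefore does not show that changes of 1.25-fold are absent. The rule for naming features without gene names allowed at most 2 higher and 2 lower; those with the smallest p in DHF minus NF were taken.

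A signature of DHF was to be made of the features past the threshold in DHF. There were 0, so the second choice fixed beforehand, the 100 features with the largest absolute moderated t, was used. Each NF and CRT animal was scored by the mean dye-corrected log2 ratio over these features, signed by the DHF coefficient. Each DHF animal was scored with a signature refitted without it.

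Measures per animal were chosen after the data were examined. A feature was called bright when its value was shared with another feature on fewer than 8 of the 16 arrays, which left 12583 features. The 12133 features that shared their value on all 16 arrays were taken as near background, without a measured signal. For each animal the dye effect estimated from the other 15 arrays was subtracted. The spread of the wall ratio (median absolute deviation times 1.4826) and the number of bright features past 2-fold were then taken. Groups were compared by exact two-sided permutation tests on animals, with Benjamini-Hochberg adjustment over 6 tests. The smallest p these can give is set by the number of splits, 462 for 6 against 5 animals and 252 for 5 against 5. For 5 against 5 it is 0.0079. Correlations between animals are across bright features, with ratios limited to 1 log2 unit on either side. Features are not independent replicates, so these correlations carry no p. No 2 arrays were copies of each other; the closest pair differed by a median of 0.056 per feature.

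Dye orientation is the only technical batch the labels give, and values within each orientation are reported. For arrays the number of animals limits the precision, and no scanner signals were used here. Alternatives planned before the data were examined were centring, scaling or quantile normalization of the arrays, no dye term or a dye term in each group, fitting only the groups of a contrast, array weights, robust eBayes, leaving out the features of lower spread, the other reading of the direction, stricter thresholds, a linear model without eBayes, and leaving out each animal. The restriction to bright features and the alternatives for the measures per animal were added afterwards. The planned averaging of probes per gene and all gene list tests needed gene names and were not run. A filter on missing values would remove nothing. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the measures per animal.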

Results

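Expression in the subendocardium of the anterior and lateral left ventricular wall was compared within each of 16 dogs. The lateral wall is supplied by the circumflex artery and the anterior wall by the left anterior descending artery. After ablation of the left bundle branch the electrical impulse reaches the lateral wall late, which makes contraction dyssynchronous. The 6 NF animals were non-failing controls. In the 5 DHF animals the left bundle branch was ablated and, 1 week later, right atrial pacing at 200 beats per minute was started and kept for 6 weeks. The 5 CRT animals underwent the same ablation and were paced at the same rate from the right atrium for 3 weeks and then from both ventricles for 3 weeks, which restores a more even activation. The design asks whether the walls differ in the non-failing heart, whether dyssynchronous failure changes that difference, and whether resynchronization changes it again. Ratios are given as log2 of the likely direction lateral over anterior; if the deposited ratio runs the other way, every sign turns.

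With values taken as turned by wall, the largest repeatable component was tied to the dye. A dye effect passed adjusted p 0.05 in 11048 features by limma, 4844 with a higher and 6204 with a lower ratio where Cy5 held the lateral wall. Fitted separately in each group, the part of the ratio that turns with dye orientation correlated across features at r = 0.47 between NF and DHF, 0.72 between NF and CRT, and 0.41 between DHF and CRT. The part that keeps its sign correlated at 0.01, -0.10 and -0.04. If the values run by dye instead, 0 features had a dye effect by limma (1407 at an unadjusted p below 0.05) and the same component is a wall difference.

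In non-failing hearts no feature passed the test for a difference between the walls. By limma, 0 features passed adjusted p 0.05, and 1672 had an unadjusted p below 0.05, where chance gives 2101.7. Over the 12583 bright features the median 95% confidence interval reached 0.097 log2 units to either side of the estimate, and the interval excluded a 2-fold mean difference of the walls for all but 11 of them. Fitted on the NF arrays alone, 1 feature passed.

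In dyssynchronous failing hearts no feature passed either, and small p-values were more frequent than in NF and CRT under most settings, but not under all. The count past adjusted p 0.05 by limma was 0, and 3035 features had an unadjusted p below 0.05. Among the bright features 1382 did, against 383 in NF and 403 in CRT. The groups share their estimate of the spread here, although DHF ratios were the widest on average. The count was still highest in DHF with a linear model without eBayes (2936, against 1844 in NF and 1906 in CRT), and with each single animal left out. Other settings went the other way. With each group fitted on its own arrays (6 in NF, 5 in DHF and 5 in CRT), the counts over all features were 1289 in DHF, 2420 in NF and 1389 in CRT. They were 1664, 2576 and 2457 with quantile normalization, and 2420, 3244 and 2104 with array weights. The interval, which uses the shared spread, excluded a 2-fold mean difference for all but 36 bright features. A single animal decided the count past adjusted p 0.05. Without DHF replicate 5, 54 features passed, 22 higher and 32 lower in the lateral wall, and 5713 had an unadjusted p below 0.05. This animal ran against all other DHF animals, so leaving it out favours higher counts, which add no separate support for a wall difference. The same limit applies to the counts without it in DHF minus NF and CRT minus DHF.

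After resynchronization 0 features passed by limma, and 1769 had an unadjusted p below 0.05. Over bright features the median interval half-width was 0.10 log2 units with 5 animals, and a 2-fold mean difference was excluded for all but 14 of them.

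The wall difference in failing hearts was set against that in non-failing hearts feature by feature, for values taken as turned by wall. By limma, 0 features passed adjusted p 0.05 in DHF minus NF, and 2884 had an unadjusted p below 0.05. The smallest adjusted p was 0.186. Feature 43268 had a log2 wall ratio of -0.19 ± 0.060 (SD, n = 6) in NF, 0.16 ± 0.12 (SD, n = 5) in DHF and -0.07 ± 0.084 (SD, n = 5) in CRT. Its difference between DHF and NF was 0.35 (SE 0.054, limma adjusted p = 0.186), and its DHF ratio was positive in 4 of 5 animals. Feature 5024 ran the opposite way, with 0.19 ± 0.040 (SD, n = 6) in NF, -0.14 ± 0.12 (SD, n = 5) in DHF and -0.0015 ± 0.067 (SD, n = 5) in CRT. Its difference was -0.33 (SE 0.049, limma adjusted p = 0.186), and its DHF ratio was negative in 5 of 5 animals. Feature 29875 differed by 0.28 and feature 1003 by -0.15, both with a limma adjusted p of 0.506; these 2 features are not bright, as their value was shared on 9 of 16 arrays. For values running by dye, the difference turned sign in all 4 features: -0.13 for feature 43268, 0.075 for feature 5024, -0.11 for feature 29875 and 0.012 for feature 1003. Without DHF replicate 5, 3 features passed, among them feature 43268, at which this animal stood apart (-0.049, against 0.18 to 0.26 in the other DHF animals).

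For the step from failure to resynchronization, 0 features passed by limma in CRT minus DHF, and 2582 had an unadjusted p below 0.05. Without DHF replicate 5, 9 features passed, 6 higher and 3 lower in CRT. In CRT minus NF 0 features passed, and 2156 had an unadjusted p below 0.05, close to the 2101.7 expected by chance. Over bright features the median interval half-width was 0.15 log2 units for CRT minus DHF and 0.14 for CRT minus NF.

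**Figure D1:**
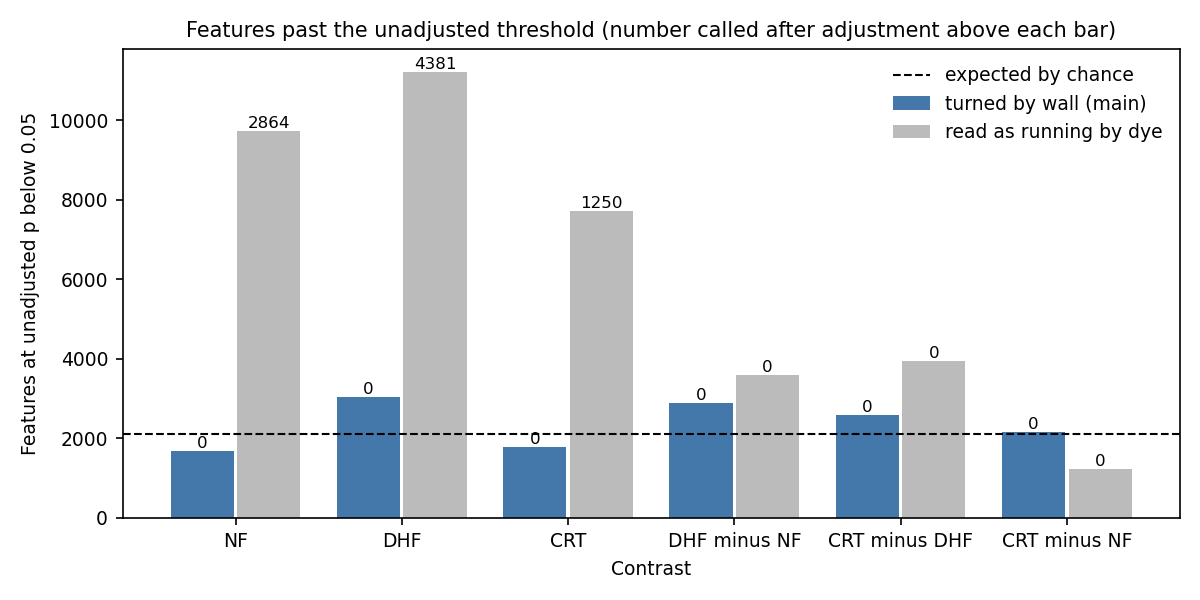
Number of features at an unadjusted p below 0.05 (vertical axis) in each of the 6 contrasts, for values taken as turned by wall (blue) and for values read as running by dye (grey), with the number past adjusted p 0.05 above each bar and the number expected by chance as a dashed line. With values turned by wall the numbers lie between 1672 and 3035 and 0 features pass in any contrast; read as running by dye, 2864, 4381 and 1250 pass within NF, DHF and CRT and 0 in the differences between groups.

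The counts within groups depend on the reading of the deposited direction. If the values ran by dye, 2864 features would differ between the walls in NF (977 higher, 1887 lower), 4381 in DHF (1945 higher, 2436 lower) and 1250 in CRT (346 higher, 904 lower), and 0 features would have a dye effect. NF and DHF would share 1338 features, 1336 of them with the same sign, where 298.5 are expected for independent lists. Both lists come from a single fit with a shared spread and dye term, so they are not independent and chance can give a larger overlap than that. The differences between groups had 0 features past the threshold under both readings. Under the reading by dye, 3586 features in DHF minus NF, 3944 in CRT minus DHF and 1237 in CRT minus NF had an unadjusted p below 0.05.

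The DHF signature did not separate resynchronized from non-failing animals when values were taken as turned by wall. Its mean score was -0.0084 ± 0.023 (SD, n = 5) in CRT and -0.0074 ± 0.014 (SD, n = 6) in NF, a difference of -0.0010 (exact two-sided permutation test, p = 0.948). With values taken as turned by wall, the signature did not carry over within its own group either as long as all 5 animals were kept. DHF animals scored with a signature made without them had a mean of -0.046 ± 0.10 (SD, n = 5), and 2 of 5 had a positive score. Without DHF replicate 5 this turned: the mean was 0.094 ± 0.089 (SD, n = 4), and 3 of 4 had a positive score. DHF replicate 5 scored -0.220, the lowest of all animals. Read as running by dye, the left-out DHF animals had a mean of 0.311 ± 0.064 (SD, n = 5), 5 of 5 were positive, and DHF replicate 5 had the highest score of all animals, 0.364. NF and CRT animals were positive too under that reading, with means of 0.292 ± 0.024 (SD, n = 6) and 0.247 ± 0.036 (SD, n = 5), a difference of -0.045 (exact permutation p = 0.030). The difference between CRT and NF was -0.056 without DHF replicate 5 (exact permutation p = 0.039) and 0.022 without DHF replicate 1 (exact permutation p = 0.048), so its sign and its call both depended on which DHF animal was left out.

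The mean spread of the wall ratio was largest in failing hearts, but the animals of the groups overlapped and the difference passed the test only under some settings. The spread of the wall ratio over bright features was 0.152 ± 0.056 (SD, n = 5) in DHF, 0.114 ± 0.028 (SD, n = 5) in CRT and 0.097 ± 0.019 (SD, n = 6) in NF. DHF animals had 63.0 ± 69.1 bright features past 2-fold between the walls (SD, n = 5), CRT animals 11.6 ± 13.8 (SD, n = 5) and NF animals 8.17 ± 5.98 (SD, n = 6). The highest count was 175, in DHF replicate 1, followed by 82 in DHF replicate 2. Over all features the spread was 0.083 ± 0.014 (SD, n = 5) in DHF and 0.070 ± 0.0068 (SD, n = 6) in NF. The difference was 0.012, against 0.056 for bright features. Over the features taken as near background the spread was alike, with 0.059 in DHF and 0.056 in NF. By exact two-sided permutation test, DHF and NF differed with p = 0.030 for the spread and p = 0.022 for the count, both 0.091 after adjustment over 6 tests, so that neither passed. With the spread taken as a standard deviation the difference was 0.093 and passed (adjusted p = 0.026, exact permutation test). Read as running by dye, the spread was 0.184 in DHF, 0.138 in CRT and 0.126 in NF, and the mean 2-fold count 68.8, 14 and 11. DHF and NF then had exact permutation p = 0.0087 for the spread (adjusted p = 0.052) and 0.015 for the count (adjusted p = 0.091). With values taken as turned by wall, the same exact permutation test of CRT against DHF gave p = 0.206 for the spread and 0.079 for the count, and of CRT against NF 0.255 and 0.699. DHF minus NF passed without DHF replicate 3 (adjusted p = 0.048 for both measures, exact permutation test) and without DHF replicate 4 (adjusted p = 0.043 for both), while the difference in counts was 27.5 without DHF replicate 1, down from 54.8. CRT minus DHF passed for the count without DHF replicate 3 (adjusted p = 0.048, exact permutation test). DHF replicates 3 and 4 had a spread within the NF range and 2-fold counts below the DHF mean. Leaving either out therefore raises the DHF mean of both measures, so these passes add no separate support for a difference.

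Within each dye orientation the order of the DHF and NF means was kept. Where Cy5 held the lateral wall, the mean spread was 0.161 over 2 DHF arrays, 0.088 over 2 NF arrays and 0.086 over 2 CRT arrays. Where it held the anterior wall, the mean was 0.147 over 3 DHF arrays, 0.101 over 4 NF arrays and 0.133 over 3 CRT arrays, with DHF values from 0.099 to 0.236 overlapping NF values from 0.074 to 0.130. An exact permutation test that exchanged animals only within an orientation gave p = 0.057 for the spread and 0.029 for the 2-fold count of DHF against NF (adjusted p = 0.159 and 0.091).

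**Figure D2:**
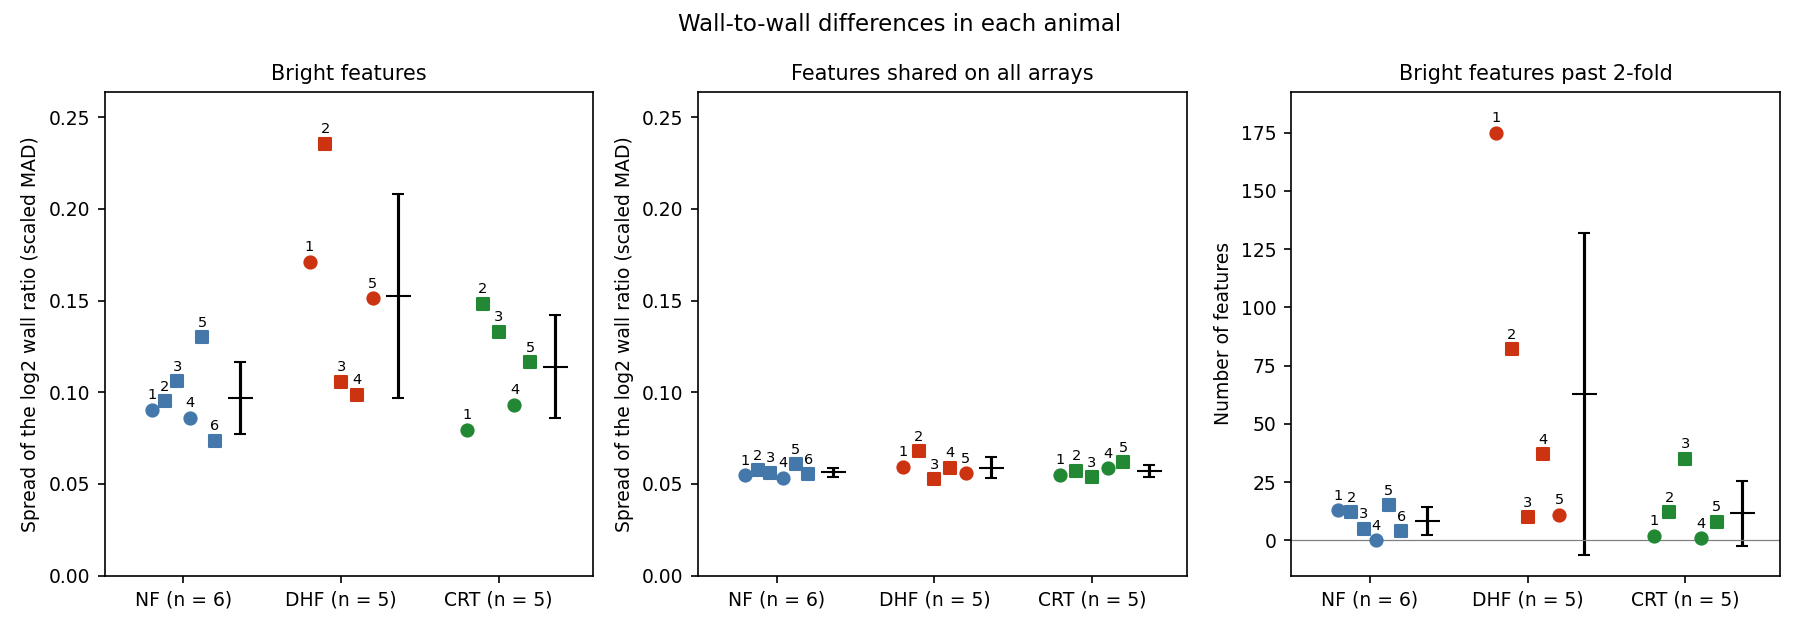
Spread of the log2 wall ratio (scaled median absolute deviation) over bright features (left) and over features near background whose value was shared on all arrays (middle), and number of bright features past 2-fold between the walls (right), for each animal by group; numbers mark replicates, circles arrays with Cy5 on the lateral wall, squares those with Cy5 on the anterior wall, and bars mean ± SD. DHF replicates 1, 2 and 5 and CRT replicates 2 and 3 lie above every NF animal in the left panel. DHF replicates 3 and 4 lie within the NF range there. The middle panel runs from 0.053 to 0.068 over all animals.

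With values taken as turned by wall, the features past 2-fold were mostly private to an animal. In DHF 268 bright features passed 2-fold in any animal, 237 of them in 1 animal and 31 in 2 or more. Of these 31 features, 24 were higher in the lateral wall of one animal and lower in that of another. In NF 39 features passed in any animal and 7 in 2 or more, 5 of them in both directions. In CRT 50 passed in any animal, and all 6 that did so in 2 or more animals went both ways. If the values run by dye, fewer went both ways: 20 of 43 in DHF, 2 of 13 in NF and 5 of 10 in CRT.

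Across bright features, with values taken as turned by wall, the mean correlation between wall ratios of animals of the same group was near that of different groups in NF and CRT, and in DHF it depended on a single animal. The mean correlation was 0.02 over the 15 pairs of NF animals, -0.07 over the 10 pairs of DHF animals, -0.08 over the 10 pairs of CRT animals and 0.002 over the 85 pairs from different groups. Without DHF replicate 5, and with the dye effect refitted, the 6 remaining DHF pairs had a mean of 0.15. Single pairs were far from 0 in both directions. The lowest value of all pairs was -0.59, between DHF replicate 2 and CRT replicate 2, and the highest was 0.44, between NF replicate 5 and DHF replicate 1. DHF replicate 5 correlated negatively with all other DHF animals, at -0.24 with replicate 1, -0.42 with replicate 2, -0.52 with replicate 3 and -0.15 with replicate 4. Read as running by dye, the same correlations were -0.10, 0.54, 0.67 and 0.39, and the mean over pairs was 0.34 in NF, 0.30 in DHF and 0.16 in CRT, against 0.24 over the pairs from different groups.

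**Figure D3:**
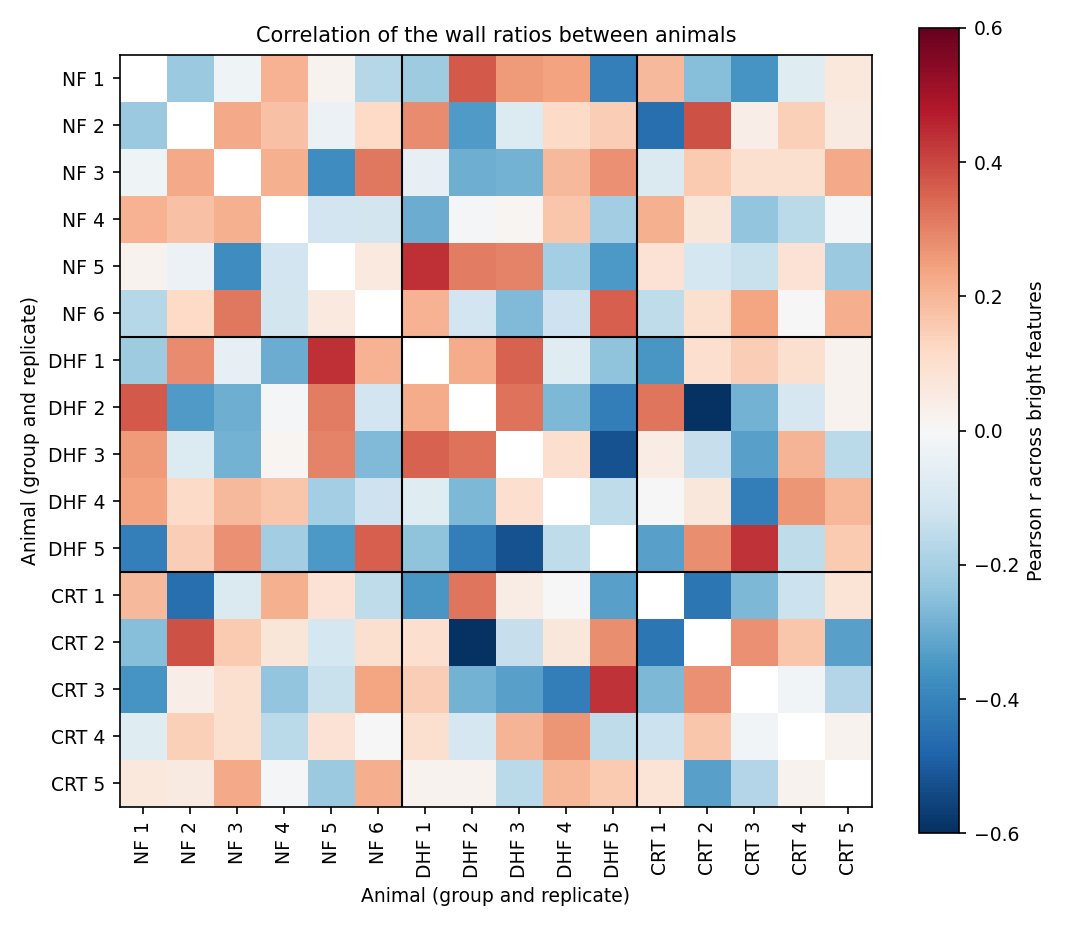
Pearson correlation across 12583 bright features of the dye-corrected log2 wall ratios of each pair of animals (red positive, blue negative; both axes list animals by group and replicate, black lines separate the groups). No group forms a red block, and the row of DHF replicate 5 is blue against the other DHF animals, from -0.52 to -0.15.

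With values taken as turned by wall, the opposition of DHF replicate 5 also set the counts within its group. With the walls of this animal exchanged in the computation, a step chosen after the data were examined, 532 features passed adjusted p 0.05 in DHF by limma. The exchange of any other animal left 0 features past the threshold in its group, with 972 to 3364 at an unadjusted p below 0.05.

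**Figure D4:**
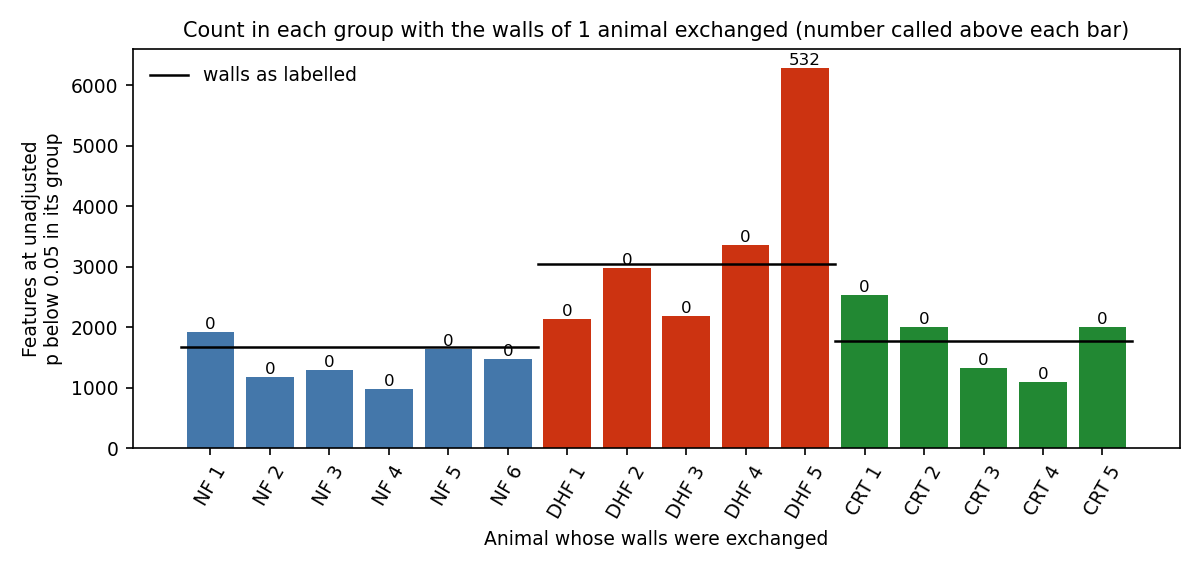
Number of features at an unadjusted p below 0.05 in an animal's own group (vertical axis) after the walls of that animal were exchanged (horizontal axis), with the number past adjusted p 0.05 above each bar; black lines mark the number with the walls as labelled. DHF replicate 5 reaches 6279 with 532 features past the threshold, and the other 15 animals have 0.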

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

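All tests of explanations in this part were chosen after the values they bear on had been seen, apart from the test on pairs of distant features.

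Among 27 groups of values examined for an animal that stands apart from its group, 1 did, where chance gives about 1.35. It was feature 43268 in DHF, with a log2 ratio of -0.049 in replicate 5 against 0.18 to 0.26 in the other DHF animals.

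With values taken as turned by wall, DHF replicate 5 ran against the other DHF animals over the bright features as a whole. Read as running by dye, it correlated at 0.54, 0.67 and 0.39 with DHF replicates 2, 3 and 4 and at -0.10 with replicate 1, so the opposition is largely absent under that reading, and the explanations weighed here apply only to the former. Turning the deposited values of this array the wrong way is argued against, since its values, signed by orientation, correlated with the dye effect of the other arrays at 0.483, on the side the labels require. Exchanging its walls before labelling raised the count of features at an unadjusted p below 0.05 in DHF by a factor of 2.07, from 3035 to 6279, and 532 features passed adjusted p 0.05 by limma (219 higher, 313 lower). The exchange of any other single animal gave 0 features past the threshold, with factors from 0.58 to 1.43. These counts add no support for an exchange of its tissue or RNA, since turning an animal that correlates negatively with all others of its group must raise the count, and no other value here decides on such an exchange, which stays open. The direction also differed between animals of the other groups, where an exchange was not ruled out either: the mean absolute correlation between animals was 0.159 in NF and 0.189 in CRT, with pairs of both signs in each. No NF or CRT animal ran against all others of its group, as DHF replicate 5 did, so a direction that varies between animals is open but not shown to go that far.

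The wider wall ratios of DHF animals were weighed against technical sources. Over the features whose value was shared on all arrays, the mean spread in DHF was 1.05 times that in NF. Over bright features it was 1.57 times. This cannot decide on noise near background, since a feature with a noisy ratio can lose its shared value and leave the former set. Isolated spots made up 4.76% of the bright features past 2-fold in DHF. For pairs of distant features that moved together in NF and CRT, noise independent between features is argued against as the only source of their ratios. Across 849 such pairs the correlation within a DHF array had a median of 0.646 (0.501 to 0.728), and simulated noise reached at most 0.284. Pairs chosen the same way had a median of 0.483 in NF and 0.553 in CRT, and simulated planted pairs 0.922. Chosen for moving together, the pairs cannot decide whether the extra spread over all bright features in DHF is independent noise. A technical trend shared by many features on an array, or RNA quality, was not tested and stays open, and so does dyssynchronous failure itself, since the difference from NF had an adjusted p of 0.0909 (exact permutation test).

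The part of the values that turns with dye orientation was read as a dye effect. The coefficient of the whole-number runs followed orientation on 16 of 16 arrays, as values turned by wall need. A wall difference in values that still run by dye would put the larger coefficient on the same side on nearly all arrays, and the larger of the 2 side counts was 10. This holds if the coefficient follows the dye and not the wall, which no value here tests.

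Exchanges and other splits of the animals gave, for values taken as turned by wall, as many features at an unadjusted p below 0.05 as the real ones. Exchanging walls within NF animals, 6 of 32 exchanges did, the walls as labelled included (real 1672, highest other 2116), so chance is not excluded. With the labelled walls included, 7 of 16 did for DHF (real 3035, median other 2978, highest other 6279). For CRT 7 of 16 did (real 1769, median other 1719, highest other 3121). These 16 exchanges are too few for a share below 0.05. Of 100 splits of the animals, the real one included, 17 reached the real count in DHF minus NF (2884, highest other 6286), 41 in CRT minus DHF (2582, highest other 6118) and 13 in CRT minus NF (2156, highest other 2729), so chance is excluded in none of these. If the values run by dye, no other exchange reached the real count in NF (9717, highest other 5188 of 32 exchanges), DHF (11222, highest other 7941) or CRT (7724, highest other 5305). For NF this is the smallest share that 32 exchanges can give. It was not adjusted over the comparisons made here, so these exchanges alone do not exclude chance. Fitted over all 16 arrays as a dye effect, the same component passed adjusted p 0.05 in 11048 features by limma. That argues against chance for this component, and the exchanges do not tell dye from wall. For the differences between groups under the reading by dye, 12, 14 and 65 of 100 splits, the real one included, reached the real count. The highest splits of values taken as turned by wall reached over 2 times the real count in DHF minus NF and CRT minus DHF. The median of the other splits was 1840 in DHF minus NF and 2309 in CRT minus DHF. Whether the animals hold a structure other than their groups cannot be told from these maxima. No such maximum was obtained for data without structure. The highest split of DHF minus NF also divided the NF animals: it put DHF replicates 4 and 5 with NF replicates 2, 3, 4 and 6.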

How the results depend on the processing

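Of 180 repeats of the 6 contrasts under other settings or without an animal, 173 also gave 0 features past the threshold. Among them, the repeats at adjusted p 0.01 and with at least 1.5-fold filter the same fit more strictly and had to give 0. Read as running by dye, NF had 2864 features, DHF 4381 and CRT 1250, and the dye effect 0. Wall and dye change places under that reading, so its dye term is the part that keeps its sign, shared by all groups. No contrast of the main fit tests that shared part, so the 0 was not fixed in advance. Fitted on its own arrays, NF had 1. Leaving out each animal gave 0 to 54 features in DHF, 0 to 3 in DHF minus NF and 0 to 9 in CRT minus DHF, each highest without DHF replicate 5 and 0 without any other animal. The dye effect passed in 20 features with at least 1.5-fold, 5619 at adjusted p 0.01 and 4358 among bright features alone (chosen after seeing the data), each from fewer features or a stricter threshold. Array weights lowered the smallest adjusted p of DHF minus NF to 0.0632. The signature difference of CRT minus NF was 0.000695 with robust eBayes, 0.0165 with a dye term in each group, -0.0454 read as running by dye (exact permutation p = 0.030), and from -0.0559 to 0.0216 without single animals; the cause was not tested. The alternatives for the spread, the 2-fold counts and the correlations between animals were chosen after seeing the data. As a standard deviation, the spread differed by 0.0932 between DHF and NF (adjusted p = 0.026, exact permutation test), and no other alternative that kept all animals passed. Without single animals the spread difference by median absolute deviation ranged from 0.0389 to 0.0693, the difference in 2-fold counts from 27.5 to 72.25 for DHF minus NF and from -69.25 to -23.7 for CRT minus DHF. Read as running by dye, DHF minus NF was -0.128 for feature 43268, -0.110 for feature 29875, 0.0750 for feature 5024 and 0.0116 for feature 1003. Of 106 repeats for these features, 1 passed, feature 43268 without DHF replicate 5. The 12133 features whose value was shared on all arrays were taken as limited by signal over background, which was not measured here.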

Other observations

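The prediction for the test in this part was written before its result was seen; the measures it uses were chosen after the data were examined.

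The features that varied most between the walls overlapped between the groups far beyond chance, although most of each list was not shared. Of the 126 bright features (1%) with the largest spread between NF animals, 50 were among the 126 with the largest spread between DHF animals, 39.6 times the 1.26 expected by chance. NF and CRT shared 44 and DHF and CRT 50, and 29 were in all 3 lists. These lists take the values as turned by wall; read as running by dye, NF and DHF shared 41, NF and CRT 43, DHF and CRT 51, and 28 were in all 3. A candidate explanation is that these features follow the site or makeup of the tissue sample, which differs from animal to animal in either direction, but features that are noisy on this array in every group would overlap as well, and without gene names no cell type was tested.

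Isolated values, past 2-fold on 1 array with all others within 0.3 log2 units, numbered 117 over all features and arrays, 38 of them on DHF replicate 4 and 21 on DHF replicate 3. Of the 117, 72 had another one on the same array within 2 numbers, or at the distance of 1 or 2 rows of the presumed spot grid with a margin of 2. For the same numbers of features drawn at random from all features, 1.23 would.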
